A study of Nitrospira moscoviensis with 9 samples.

How the data were processed

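Transcript levels of Nitrospira moscoviensis, a nitrite-oxidising bacterium that fixes carbon dioxide, were measured by RNA sequencing of biomass from a continuously stirred bioreactor fed with nitrite. Samples were taken on day 112 (T1), day 120 (T2) and day 127 (T3), with 3 libraries per day and 9 libraries in all. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, small RNAs were removed with a column kit, ribosomal RNA was depleted with MICROBExpress, and libraries were made with an Ion Torrent total RNA kit. The labels call the libraries of a day technical replicates, and all of them came from a single reactor. The p-values therefore measure the spread between technical replicates, and the sampling day cannot be separated from anything else that differed between the days.

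The deposited table of read counts gives whole-number counts per gene and library, not normalized, per the file headers. Counting with featureCounts and testing with DESeq2 are named in the submitters' processing notes, without versions. The aligner, the genome build, and the settings for reads that match several genes and for strand are not given in the sources used here. A second table deposited by the authors holds, per gene, the position on 1 replicon, the length, names from the RefSeq and MicroScope annotations, and the mean RPKM over the libraries. The same deposited table holds, from DESeq2 per the file headers, log2 fold changes with standard errors, and p-values rounded to 2 decimals by the authors, for the time course and for each pair of days. Gene names and positions were taken from this table as the authors gave them. No genome sequence was used here, so similarity between gene copies and GC content were not checked.

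The count table held 4391 genes, of which 124 had no read in any library, and 509686 reads in all. It held no genes for ribosomal, transfer or other stable RNA. The total count per library ran from 43441 to 86026, a ratio of 1.98, and the median gene had 34 reads over the 9 libraries together. At these totals a count of 3 equals between 34.9 and 69.1 RPKM for a gene of 1 kb. That count is about the 95% upper limit on the expected count of a gene with no read, and not a maximum. Shares of reads in a single library were given 95% Wilson intervals. Reads carried no molecular identifiers and include PCR copies, so intervals and floors cover counting error only. The RPKM values were recomputed from the counts, and their means matched those in the authors' deposited table within 0.05 for all 4391 genes.

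Counts were compared with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by sampling day at its minimum count of 10, a model with a term for each day over all 9 libraries, and the quasi-likelihood F test (glmQLFit and glmQLFTest). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, for each pair of days and for any difference among the 3 days. The filter left 1211 genes (27.6% of the table) that held 83.8% of the reads. The common dispersion was 0.0243, which is a coefficient of variation of 15.6% between technical replicates beyond counting noise. Standard errors of log2 fold changes come from this fit. A gene was counted as equivalent between days when the 90% interval of its log2 fold change lay inside 2-fold in both directions. Levels by day are TMM-scaled CPM (counts scaled to a common library total), as mean and SD of 3 libraries.

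Gene lists for the functions of this organism were written as patterns over gene symbols and product names, 27 lists in all, and 107 members whose product named another function were dropped once the table was at hand, by reading the product alone. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over 25 lists. The same test with a correlation estimated from the data stands beside each call. The list of stable RNA genes was empty, and the list of flagellum and chemotaxis genes had too few tested members. Genes named in the text were chosen by rule. The rule took the 8 largest rises and the 8 largest falls per comparison among called genes with a known product, a mean of at least 10 CPM and libraries of the 2 days that did not overlap, with 2 of each among genes of unknown product. It also took the 3 members of each list with the smallest p, the 3 most abundant of each list, the 20 genes with the highest RPKM, and every nitrite oxidoreductase gene. The groups, tests, lists, naming rule and the first set of alternatives were fixed before the data were examined.

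The procedure was tested on simulated counts for the T3 vs T1 comparison with 1203 tested genes. Among changed genes that passed the filter, it called 75.6% of the 2-fold and 95.7% of the 4-fold changes with the right sign. Of its calls 4.85% were false. The simulation changed 200 genes, more than were called in any real comparison, which loosens the Benjamini-Hochberg threshold. The shares called therefore need not hold for the real comparisons. Of the unchanged simulated genes 76.7% were counted as equivalent, and so were 4.44% of those changed 2-fold.

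Before libraries were averaged, each pair was compared by a chi-square test over genes with an expected count of at least 5. The statistic per degree of freedom was 1.52 to 2.12 within a day and 1.66 to 3.59 between days. PCR copies raise this statistic, so it does not show how far the sampled molecules differed. No pair was treated as 1 library deposited more than once, and all 9 were counted as the labels list them. The alternatives tried were DESeq2 size factors (RLE) and library size alone in place of TMM, no filter and a filter of 50 reads, the replicate number as a block, robust dispersion, only the compared days in the fit, DESeq2 1.42.0, a prior count of 0.5 for the gene lists, TPM in place of RPKM, and each library left out in turn. Alternatives without the nitrite oxidoreductase genes, with all libraries thinned to 43441 reads, and with each library's trend over gene length removed were added after seeing the data.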

Results

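Nitrospira moscoviensis gains energy by oxidising nitrite to nitrate with nitrite oxidoreductase, a membrane-bound enzyme whose alpha and beta subunits its genome encodes in several copies. Transcription in a continuous culture on nitrite was compared between 3 sampling days, T1 (day 112), T2 (day 120) and T3 (day 127), with 3 technical replicate libraries each, to see how stable the culture was. The deposited counts of reads per gene totalled 83176, 49513 and 86026 in T1 replicates 1 to 3, 59067, 50945 and 45463 in T2, and 45163, 43441 and 46892 in T3. Between 3361 and 3742 of the 4391 genes had a read in any single library. On log2 CPM across genes, Pearson's r was 0.860 to 0.914 between libraries of a day and 0.821 to 0.894 between libraries of different days, and genes are not independent replicates.

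Nitrite oxidoreductase held some of the most abundant transcripts of the culture, and its alpha subunit had the highest mean RPKM over the 9 libraries. The alpha subunit NITMOv2_RS20860 (4282377 to 4285814 on the replicon) had 26030 ± 6948 RPKM (SD, n = 9), which was 8.95% of all reads, against 97.6 for the median gene. The membrane subunit NITMOv2_RS16660 followed with 18780 ± 1845 RPKM, and the beta subunit NITMOv2_RS20840 (4273898 to 4275187) had 15636 ± 3867. Another membrane-associated gene of the enzyme, NITMOv2_RS16730, had 4743 ± 840. The remaining genes among the 20 with the highest RPKM included an exported protein of unknown function, NITMOv2_RS11530 (16048 ± 7095). Others of the same kind included NITMOv2_RS08105 (12065 ± 1212) and NITMOv2_RS20570 (9262 ± 948). Also among the 20 were the Hsp20 chaperone NITMOv2_RS09640 (5778 ± 1242), a monohaem cytochrome c, NITMOv2_RS16935 (5393 ± 1733), and the RNA-binding protein rbpA (5002 ± 1255). So was NITMOv2_RS18310 (4464 ± 1036), an exported protein of unknown function annotated as a putative multicopper oxidase. The regulator nifA (NITMOv2_RS20830, 4271448 to 4273085), which is separated from the beta subunit NITMOv2_RS20840 by NITMOv2_RS20835, had 5316 ± 909 RPKM. On T3 alone, the exported protein NITMOv2_RS11530 stood above NITMOv2_RS20860, at 22452 ± 7381 RPKM against 19454 ± 4390 (SD, n = 3).

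**Figure D1:**
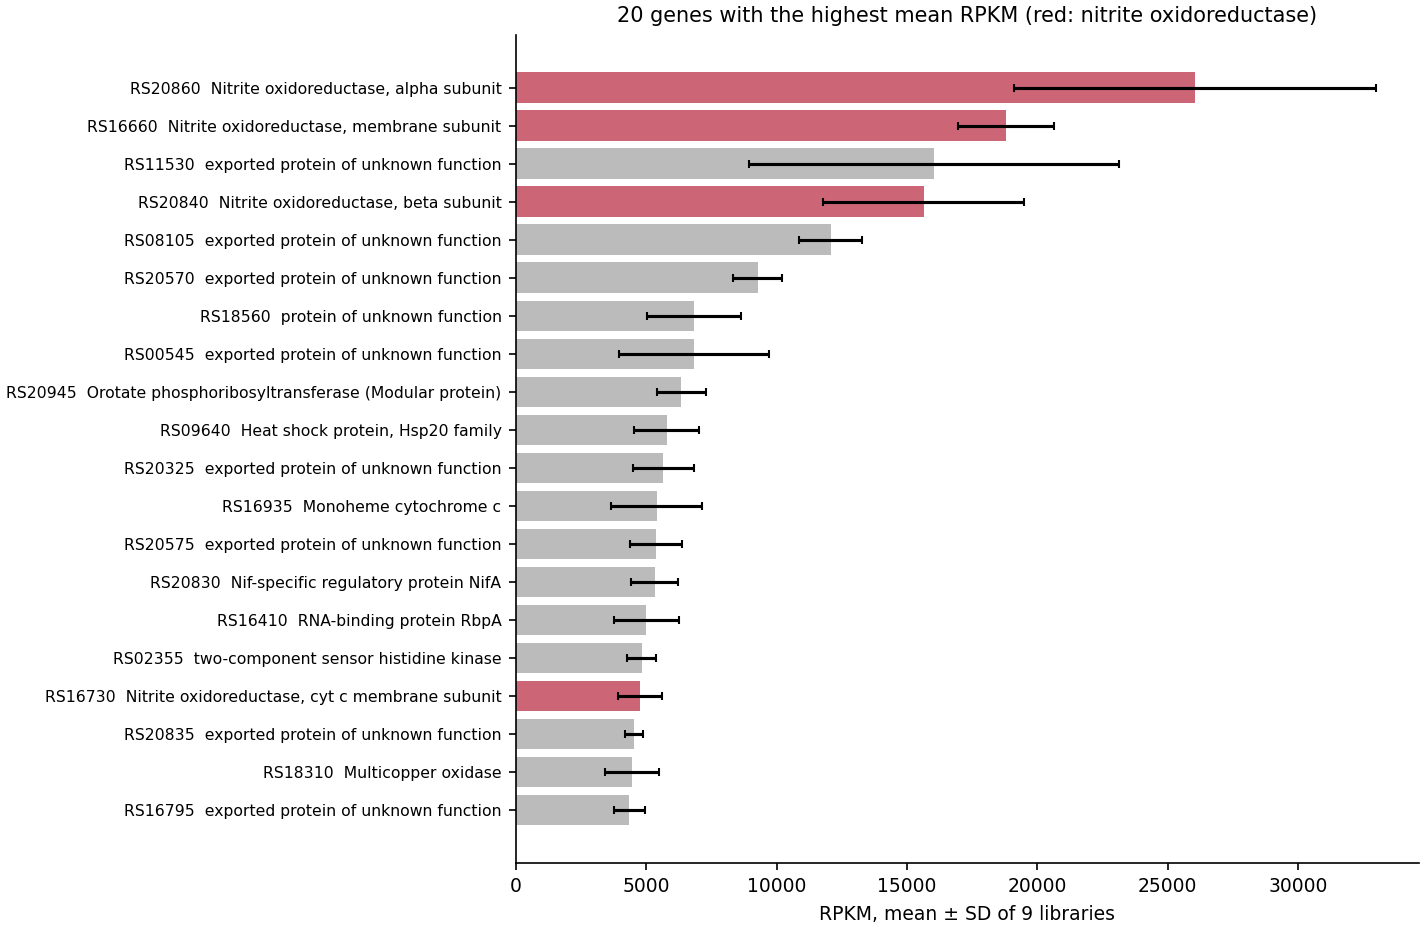
The 20 genes with the highest mean RPKM as bars from 0, with the SD over 9 libraries as error bars and nitrite oxidoreductase genes in red. The alpha subunit NITMOv2_RS20860 stands highest, at 26030 RPKM.

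The copies of nitrite oxidoreductase differed widely in level. The alpha and beta genes lay at 4 places: NITMOv2_RS20860 and NITMOv2_RS20855 with NITMOv2_RS20845 and NITMOv2_RS20840 between 4273898 and 4285814, NITMOv2_RS01125 and NITMOv2_RS01130 at 243295 to 248060, NITMOv2_RS18510 and NITMOv2_RS18515 at 3799026 to 3803791, and NITMOv2_RS18530 and NITMOv2_RS18535 at 3807932 to 3812697. Below NITMOv2_RS20860, the alpha copies ranked NITMOv2_RS01130 (3423 RPKM), NITMOv2_RS20845 (2049), NITMOv2_RS18515 (1461) and NITMOv2_RS18535 (1239). Below NITMOv2_RS20840, the beta copies ranked NITMOv2_RS01125 (3469 RPKM), NITMOv2_RS20855 (2943), NITMOv2_RS18510 (1800) and NITMOv2_RS18530 (1482). The membrane genes NITMOv2_RS03435, NITMOv2_RS16630 and NITMOv2_RS19340 had 725, 352 and 37.8 RPKM. The settings for reads that match several copies are not given in the sources used here, so the levels of single copies are uncertain. The loci were chosen for description after their values were seen.

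Together the nitrite oxidoreductase genes took 17.8 ± 3.71% of the reads (SD, n = 9), with 17.6 ± 1.94% on T1, 21.5 ± 2.42% on T2 and 14.2 ± 2.21% on T3 (SD, n = 3 each). The highest library was T2 replicate 1 with 24.1% (95% Wilson interval 23.72% to 24.41%), and the lowest was T3 replicate 2 with 11.7% (11.43% to 12.03%). The 20 genes with the most reads in each library together took 26.2 ± 2.23% of reads on T1 and 30.2 ± 3.03% on T2. They were picked by read count, library by library, and are not the set of 20 with the highest RPKM. On T3 they took less than on either other day, so the share left for all others differed between days.

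**Figure D2:**
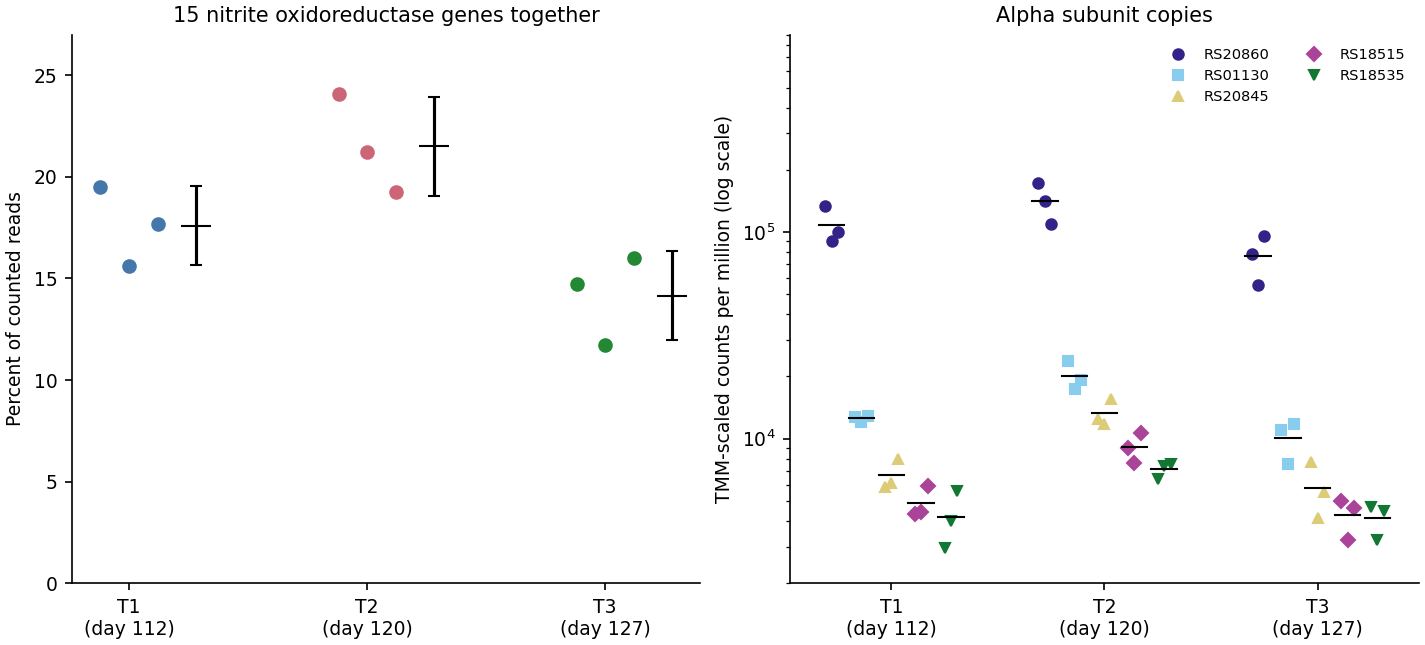
Left, percent of counted reads in nitrite oxidoreductase genes by sampling day, with points for the 3 libraries of a day and their mean and SD beside them; right, TMM-scaled CPM (log axis) of the alpha subunit copies, with points for libraries and lines for means. The alpha copy NITMOv2_RS20860 averaged 141074 CPM on T2 and 76386 on T3.

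Genes for carbon fixation, respiration and nitrogen uptake were expressed at moderate levels. The reductive tricarboxylic acid cycle and carbon dioxide fixation list took 1.81 ± 0.112% of reads (SD, n = 9), led by forA with 1394 ± 208 RPKM. Nitrogen assimilation took 1.71 ± 0.122%, with glnA at 2324 ± 374 RPKM and the cyanase gene cynS at 1731 ± 645. Complex I (NADH dehydrogenase) took 0.709 ± 0.110% of reads, with its nuoF gene NITMOv2_RS18680 at 556 ± 138 RPKM. Respiratory complexes III and IV took 1.20 ± 0.104%, led by a cytochrome bd-like oxidase, NITMOv2_RS16745, at 2645 ± 395 RPKM. The ATP synthase genes took 0.466 ± 0.0386%, with atpF at 2160 ± 334 RPKM. Chaperones and proteases took 2.73 ± 0.192%, where groEL had 3426 ± 643 RPKM after the Hsp20 gene NITMOv2_RS09640. Translation factors and tRNA synthetases together took 2.18 ± 0.227%, with fusA at 1647 ± 236 RPKM, and ribosomal proteins 1.74 ± 0.219%.

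Over the 3 days together, 30 of 1211 tested genes differed at a Benjamini-Hochberg adjusted p under 0.05 (edgeR quasi-likelihood F test). Nitrite oxidoreductase made up 7 of the 14 genes that stood highest on T2, among them the alpha copies NITMOv2_RS20845, NITMOv2_RS18515, NITMOv2_RS01130, NITMOv2_RS18535 and NITMOv2_RS20860. A further 11 genes were highest on T3 and 5 on T1. DESeq2 called 21 genes, and 178 had a raw p under 0.05. The number called lay between 12 and 32 with any single library left out. It was lowest at 12 without T1 replicate 2 or T2 replicate 1, 15 without T3 replicate 2, and 17 without T1 replicate 1 or T3 replicate 3.

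From T1 to T2, the question was whether transcription moved over the first interval, and 3 of 14 tested nitrite oxidoreductase genes rose. The alpha copy NITMOv2_RS20845 rose from 6637 ± 1165 to 13248 ± 2008 CPM (SD, n = 3), and the alpha copy NITMOv2_RS18515 and the beta copy NITMOv2_RS20855 rose by log2 0.90 ± 0.20 and 0.87 ± 0.20 (SE). The abundant alpha copy NITMOv2_RS20860 did not pass, with a log2 fold change of 0.38 ± 0.21 (edgeR, Benjamini-Hochberg adjusted p 0.492). The cytochrome c gene NITMOv2_RS16935 rose from 1840 ± 639 to 3584 ± 622 CPM, and a pair of Hsp20 chaperone genes, NITMOv2_RS18055 and NITMOv2_RS02790, rose by log2 0.81 ± 0.20 and 0.88 ± 0.22. The gene nadE (NITMOv2_RS05865) rose from 277 ± 27.1 to 649 ± 215 CPM, and NITMOv2_RS01115, of unknown function, from 312 ± 31.5 to 734 ± 191. The only fall was in an exported protein of unknown function, NITMOv2_RS11675, from 1212 ± 279 to 362 ± 150 CPM, by log2 -1.73 ± 0.29 (edgeR, Benjamini-Hochberg adjusted p 5.45e-04).

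In all, 9 genes changed between T1 and T2, 8 up and 1 down, and 148 had a raw p under 0.05. Of these, 3 changed at least 2-fold, 2 up and 1 down, against 1 up and 1 down with RLE scaling and 0 up and 1 down with library size alone. With library size alone, 1 gene was called, the fall in NITMOv2_RS11675, and the median log2 fold change of all tested genes moved from 0.05 to -0.10 (from 0.01 to 0.23 for T3 vs T2, and from 0.01 to 0.08 for T3 vs T1). Only NITMOv2_RS11675 passed in each of the 9 fits with 1 library left out. The count was 2 without T1 replicate 1, 1 without T1 replicate 2, 14 without T1 replicate 3, 1 without T2 replicate 1 and 4 without T2 replicate 2. The Hsp20 gene NITMOv2_RS18055 passed in 0 of those fits, NITMOv2_RS02790 in 1, and the 3 nitrite oxidoreductase genes in 4 or 5.

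As a group, 13 of the 14 tested nitrite oxidoreductase genes were higher on T2 than on T1, with a median log2 fold change of 0.46. The list passed camera with a Benjamini-Hochberg adjusted p of 1.44e-04 over 25 lists, but not with an estimated correlation, where it was 0.507, the highest over its alternatives (the lowest was 5.78e-05). Within it, 3 genes passed over all genes tested and 7 when adjusted over the list alone. In complex I, 13 of 15 tested genes had lower estimates on T2, with a median of -0.21, nuoB at -1.03 ± 0.42 (SE) and nuoN at -1.05 ± 0.44. Its camera adjusted p (Benjamini-Hochberg) was 0.0147, and 0.507 with an estimated correlation. The complex I call was also lost without T1 replicate 1 (camera, Benjamini-Hochberg adjusted p 0.0635), T2 replicate 1 (0.0950) or T2 replicate 2 (0.0589), and in thinned libraries (0.125), and its adjusted p ran from 0.00550 to 0.507 over all alternatives run for it. Among the complex I genes 0 passed singly, 2 had a raw p under 0.05, and DESeq2 called 0. The chaperones, of which 2 of 25 rose, had a list median of 0.19 and did not pass (camera, Benjamini-Hochberg adjusted p 0.233).

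From T2 to T3, the second interval, 6 of 14 tested nitrite oxidoreductase genes fell. The abundant alpha copy NITMOv2_RS20860 fell from 141074 ± 31781 to 76386 ± 20157 CPM (SD, n = 3), by log2 -0.89 ± 0.21 (SE). The alpha copies NITMOv2_RS20845 (-1.19 ± 0.21) and NITMOv2_RS18515 (-1.09 ± 0.21) and the beta copies NITMOv2_RS20855 (-0.97 ± 0.20) and NITMOv2_RS18530 (-0.94 ± 0.21) fell too, and the alpha copy NITMOv2_RS01130 fell from 20215 ± 3306 to 10115 ± 2251 CPM. The abundant beta copy NITMOv2_RS20840 had a log2 fold change of -0.78 ± 0.21 and did not pass (edgeR, Benjamini-Hochberg adjusted p 0.0706). The membrane genes had log2 fold changes of -0.31 for NITMOv2_RS16660, 0.06 for NITMOv2_RS16730, 0.41 for NITMOv2_RS03435 and 0.47 for NITMOv2_RS16630, none of which passed, and their difference from the other subunits was not tested. The putative multicopper oxidase NITMOv2_RS18310 fell from 33250 ± 3630 to 17666 ± 1366 CPM. A metal efflux gene of the CzcB type, NITMOv2_RS17945, fell from 1003 ± 195 to 461 ± 88.5 CPM.

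The exported protein NITMOv2_RS11675, which had fallen over the first interval, rose again from 362 ± 150 to 821 ± 165 CPM. The cell envelope gene waaE (NITMOv2_RS16160) rose by log2 2.37 ± 0.56 (SE), although its libraries overlapped between days, at 185 ± 218 CPM on T2 and 913 ± 659 on T3. With 1 library left out the log2 fold change of waaE lay between 1.63 and 3.87, and the call was lost without T2 replicate 1, T2 replicate 2 or T3 replicate 1, with robust dispersion and in DESeq2. The Hsp20 genes NITMOv2_RS18055 and NITMOv2_RS09640 had log2 fold changes of -0.79 and -0.75 and did not pass (edgeR, Benjamini-Hochberg adjusted p 0.0625 and 0.0863). In all, 10 genes changed, 2 up and 8 down, and 5 of them at least 2-fold, 2 up and 3 down. With library size alone the split was 4 up and 6 down, and 3 up and 0 down at 2-fold or more.

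Of these 10 genes, 0 passed in every fit with 1 library left out, and NITMOv2_RS20845 and NITMOv2_RS18515 passed in 8 of 9. The abundant copy NITMOv2_RS20860 passed in 4 of 9. It also lost the threshold with only the compared days in the fit and with the trend over gene length removed (log2 -0.79). The other called nitrite oxidoreductase genes kept the threshold under both. Without T3 replicate 2, none of the called nitrite oxidoreductase genes passed. The count was 2 without T2 replicate 1, 3 without T2 replicate 2, 1 without T3 replicate 2, and between 7 and 12 otherwise. The nitrite oxidoreductase list had a median log2 fold change of -0.78, with 11 of 14 genes lower on T3. It passed camera with a Benjamini-Hochberg adjusted p of 4.37e-07, and not with an estimated correlation (0.566, the highest over its alternatives, where the lowest was 9.33e-08). Within it 6 genes passed over all genes tested and 10 when adjusted over the list alone. The T2 libraries enter both intervals, so the rise to T2 and the fall after it are not independent of each other.

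From T1 to T3, across the whole period, a hydrogenase was among the clearest rises. Its small subunit hupS (NITMOv2_RS07505, 1534775 to 1535737) rose from 378 ± 85.5 to 1131 ± 289 CPM (SD, n = 3), by log2 1.58 ± 0.28 (SE; edgeR, Benjamini-Hochberg adjusted p 0.00159). The large subunit NITMOv2_RS07510 beside it (1535780 to 1537375) rose from 1533 ± 161 to 3344 ± 1270 CPM. The ribosomal protein genes rpmE and rplU rose by log2 1.39 ± 0.34 and 1.17 ± 0.30, and the initiation factor infC by 1.18 ± 0.30. Each of rpmE, rplU and infC passed in only 3 of the 9 fits with 1 library left out. All of them lost the threshold in DESeq2 and with the trend over gene length removed. The gene infC was the 1 of 28 tested translation factor and tRNA synthetase genes that rose, also when adjusted over the list alone, and that list did not pass (camera, Benjamini-Hochberg adjusted p 0.406). The RNA-binding protein rbpF (NITMOv2_RS16860) rose from 1000 ± 260 to 2011 ± 382 CPM, and prsA rose by log2 0.97 ± 0.24.

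A histidine kinase, NITMOv2_RS12505, fell from 785 ± 100 to 251 ± 24.7 CPM (SD, n = 3), by log2 -1.65 ± 0.31 (SE). The CzcB-type gene NITMOv2_RS17945 (-1.08 ± 0.28), NITMOv2_RS22985 (-0.96 ± 0.22) and the putative multicopper oxidase NITMOv2_RS18310 (-0.72 ± 0.18) fell too. The unknown gene NITMOv2_RS06435 had the largest rise, from 54.6 ± 27.4 to 318 ± 76.1 CPM. That rise rests on few reads, 5, 1 and 5 in T1 replicates 1 to 3 and 10, 16 and 12 in T3. The call was lost in DESeq2 and without T1 replicate 2, T3 replicate 2 or T3 replicate 3. The abundant exported protein NITMOv2_RS11530 rose from 2376 ± 753 to 5323 ± 1953 CPM. The unknown genes NITMOv2_RS01115 and NITMOv2_RS00200 rose by log2 1.13 and 1.08, and are named after their values were seen. No nitrite oxidoreductase gene passed between T1 and T3, where 3 of 14 had a raw p under 0.05 and DESeq2 called 0.

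**Figure D3:**
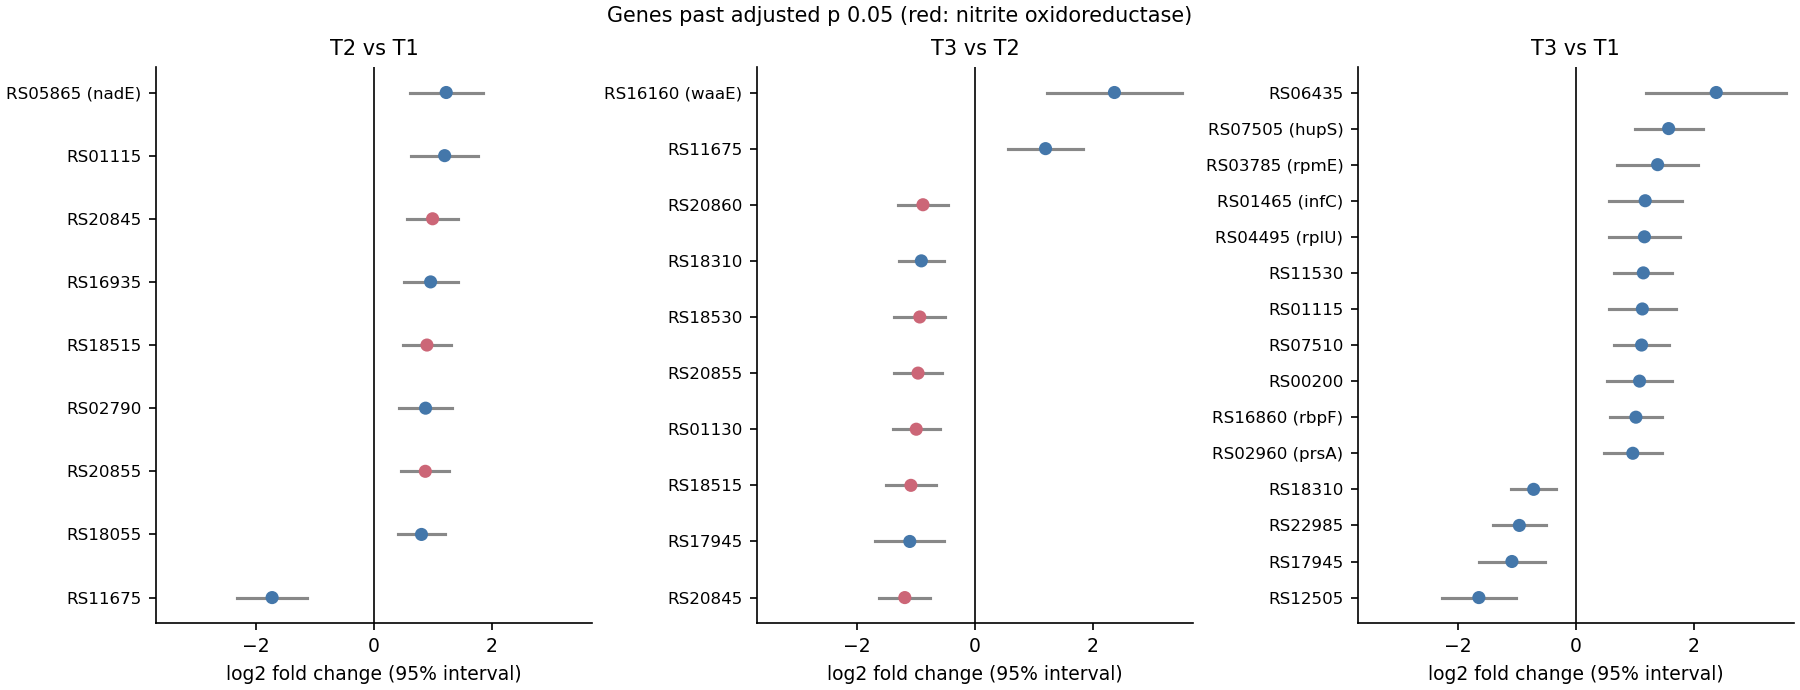
Log2 fold change (x axis, points) with its 95% interval (lines) of each gene called in a comparison of sampling days, with a panel per comparison and nitrite oxidoreductase genes in red. Nitrite oxidoreductase genes lie to the right of 0 in T2 vs T1 and to the left in T3 vs T2.

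In all, 15 genes changed from T1 to T3, 11 up and 4 down, and 12 of them at least 2-fold, 10 up and 2 down. With library size alone, 17 rose and 3 fell, and 14 up and 1 down at 2-fold or more. Only hupS and NITMOv2_RS12505 passed with each library left out. The count was 8 without T1 replicate 1, 3 without T1 replicate 2, 6 without T3 replicate 2, 2 without T3 replicate 3, and 13 to 20 otherwise. DESeq2 called 7 genes, 8 were called with libraries thinned to 43441 reads, and 5 with the trend over gene length removed.

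The ribosomal protein genes were the only list that passed between T1 and T3, with 31 of 41 tested genes higher on T3 and a median log2 fold change of 0.24 (camera, Benjamini-Hochberg adjusted p 0.0120). With an estimated correlation the adjusted p was 0.221, with the trend over gene length removed 0.287, and without T3 replicate 2 0.0777, none of which passed (camera, Benjamini-Hochberg). Over all alternatives run for the ribosomal list the adjusted p ran from 0.00593 to 0.287. Of its genes 2 rose over all genes tested and 5 when adjusted over the list alone. Their share of reads was 1.56 ± 0.0539% on T1 and 2.02 ± 0.0929% on T3 (SD, n = 3). The formate and hydrogen list, which holds the hydrogenase, had a median of 0.03 over 7 tested genes and did not pass (camera, Benjamini-Hochberg adjusted p 0.406), with 2 genes up over all genes tested and 2 adjusted over the list alone. The regulators had a median of -0.20 (adjusted p 0.103, camera with Benjamini-Hochberg), with the histidine kinase NITMOv2_RS12505 the 1 of 78 that fell.

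**Figure D4:**
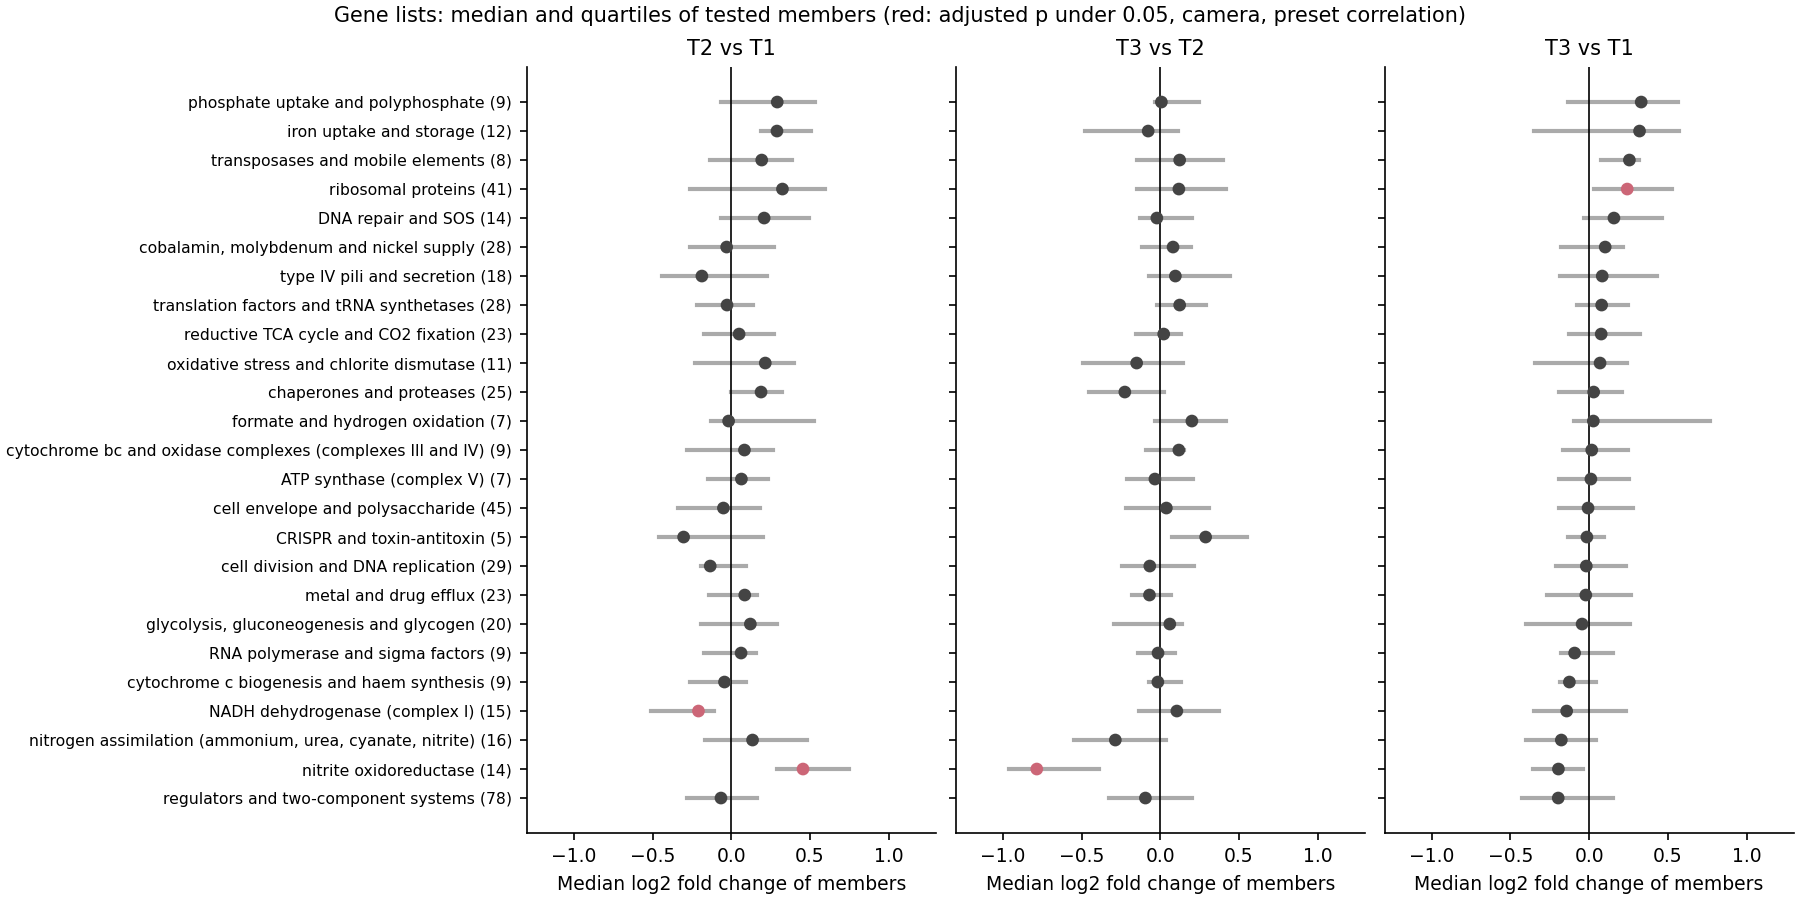
Median log2 fold change (x axis) of each gene list in each comparison of sampling days, with lines from the lower to the upper quartile, the number of tested members in parentheses, and red points where camera with a preset correlation passed. Nitrite oxidoreductase lies at 0.46 in T2 vs T1 and -0.78 in T3 vs T2.

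Most tested genes stayed within 2-fold between the first and last day. For 865 of 1211 genes (71.4%) the 90% interval of the T3 vs T1 fold change lay inside 2-fold, against 889 for T2 vs T1 and 844 for T3 vs T2. Among 4 equal classes of expression the share was 47.9% in the lowest and 90.8% in the highest. The estimate itself lay within 2-fold for 96.8% of genes. Of the 14 tested nitrite oxidoreductase genes, 13 had their 90% interval inside 2-fold for T3 vs T1, 7 for T2 vs T1 and 4 for T3 vs T2. The share of genes equivalent among the 1211 says nothing of the genes below the filter, which were not tested.

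In the authors' deposited table, 21 genes had an adjusted p under 0.05 (DESeq2) in the time course, 7 in T1 vs T2, 7 in T1 vs T3 and 9 in T2 vs T3 as a pair. The alpha copy NITMOv2_RS20860 has a T2 vs T3 log2 fold change of -0.9 in the time-course columns of the authors' deposited table and -0.17 in its pairwise columns. The putative multicopper oxidase NITMOv2_RS18310 has -0.92 and -0.56. The pairwise T2 vs T3 fold change in the authors' deposited table equals the sum of those of T1 vs T2 and T1 vs T3 within 0.01 for 4267 of 4267 genes. The time-course column of the authors' deposited table equals their difference for 4267. The 2 columns of the authors' deposited table differ in sign for 2059 genes (48.3%). Of the 9 genes called in the pairwise columns of the authors' deposited table, among them hupS, NITMOv2_RS07510, nifA and rbpF, 1 was called by edgeR for T3 vs T2 here. A DESeq2 fit of the deposited counts called 12 genes for the difference, of which 0 were among those 9.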

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

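The log2 fold changes of the 34 calls were followed through 655 values under the alternatives, of which 436 kept their direction and their side of the threshold, 219 kept their direction and lost the threshold, and 0 reversed. The nitrite oxidoreductase and complex I lists in T2 vs T1, the nitrite oxidoreductase list in T3 vs T2 and the ribosomal list in T3 vs T1 were lost with an estimated correlation (0, 0 and 0 lists passed in the 3 comparisons, against 2, 1 and 1). With library size alone, 1 gene passed in T2 vs T1 (9 in the fit with TMM), 1 at least 2-fold (3), and 3 at least 2-fold in T3 vs T2 (5). Without a filter, 6 passed at least 2-fold in T2 vs T1 and 9 in T3 vs T2, 2 lists passed in T3 vs T2, and 1081 genes were equivalent between T1 and T3, since more genes were tested. With the filter of 50 reads, 142 genes were tested, which left 1 gene at least 2-fold in T2 vs T1, 2 in T3 vs T2, 7 genes and 3 at least 2-fold in T3 vs T1 (15 and 12), 131 equivalent (865) and 16 over the 3 days (30). Robust dispersion gave 5 at least 2-fold in T2 vs T1. With only the compared days, 2 genes and 1 at least 2-fold passed in T2 vs T1, and 3 at least 2-fold in T3 vs T2, with fewer libraries in the fit. DESeq2 gave 1 and 3 at least 2-fold in T2 vs T1 and T3 vs T2, and 7 genes and 2 at least 2-fold in T3 vs T1.

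The alternatives chosen after seeing the data were the fits without nitrite oxidoreductase, with thinned libraries and with the length trend removed. Without the nitrite oxidoreductase genes, which takes them from the count, 1 gene and 1 at least 2-fold passed in T2 vs T1, 2 and 1 in T3 vs T2, 19 over the 3 days, and 1 list in T2 vs T1 and 0 in T3 vs T2. Thinned to 43441 reads, 6 passed at least 2-fold in T2 vs T1, 8 and 6 at least 2-fold in T3 vs T1, and 1 list in T2 vs T1. With the length trend removed, 5 passed at least 2-fold in T2 vs T1, 2 in T3 vs T2, 5 and 5 at least 2-fold in T3 vs T1, and 0 lists in T3 vs T1. With 1 library left out in turn, the count ran from 1 to 14 genes in T2 vs T1 (1 to 13 at least 2-fold), 1 to 12 in T3 vs T2 (1 to 9) and 2 to 20 in T3 vs T1 (2 to 18). It ran from 12 to 32 genes over the 3 days and from 737 to 920 equivalent genes. The lists passed ran from 1 to 2 in T2 vs T1, 1 to 2 in T3 vs T2 and 0 to 1 in T3 vs T1. Except where fewer genes or libraries were tested, the cause was not tested.

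With the replicate block, 12, 16 and 18 genes passed in T2 vs T1, T3 vs T2 and T3 vs T1. Replicate numbers did not pair the samples: deviations from the day means correlated at -0.12 to 0.13 over 9 pairs with the same number, and 3 of 9 libraries correlated best with their own number. The alternative without stable RNA genes was not run, since the table holds none. For all 20 of the most abundant genes by RPKM, the mean TPM differed from the mean RPKM by less than the SD of the RPKM. The ratio of TPM to RPKM was 0.968 to 0.986, and genes were not ranked anew by TPM. Depth limits what could be tested, 1211 of 4391 genes. In the simulated counts, with 200 genes changed, edgeR called 75.6% of the 2-fold changes that passed the filter, and DESeq2 38.9%. Genes below the filter could not be called, and with fewer genes changed the share called could be lower.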

Other observations

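The explanations weighed here were chosen after the results they bear on had been seen, while the edgeR tests and the fits with 1 library left out were fixed before the data were examined. The hydrogenase genes hupS and NITMOv2_RS07510, which rose from T1 to T3, lay in between on T2, going from 334 RPKM on T1 to 600 on T2 and 1030 on T3 for hupS, and from 817 to 1136 and 1832 for NITMOv2_RS07510. The gene after them, NITMOv2_RS07515, had 638, 490 and 1132 RPKM and did not pass between T1 and T3 (log2 0.72; edgeR, Benjamini-Hochberg adjusted p 0.455). The maturation genes hypF and hypE had log2 fold changes of -0.04 and -0.15, and the regulator hoxA 0.42, none of which passed. Whether the structural genes differ from the rest of the locus was not tested, and the locus was chosen after its values were seen.

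The flagellum and chemotaxis list, too weakly expressed for a test, took 0.0841 ± 0.0135% of reads (SD, n = 9), with a read for 47 of its 57 members and a median member at 6.63 RPKM. The chlorite dismutase gene cld2 (NITMOv2_RS11680), beside the exported protein NITMOv2_RS11675 that fell from T1 to T2, had a log2 fold change of 0.85 ± 0.28 (SE) over the same interval and did not pass (edgeR, Benjamini-Hochberg adjusted p 0.143).

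Technical explanations were weighed for the lower list median of nitrite oxidoreductase on T3 than on T2. With the trend over gene length removed, the list median went from -0.78 (SD 0.55) to -0.76 (SD 0.52) and the camera adjusted p (Benjamini-Hochberg) was 1.09e-06, which argues against gene length. These list tests use the preset correlation, and with an estimated correlation the list did not pass (adjusted p 0.566, camera with Benjamini-Hochberg). With 1 library left out, the highest adjusted p of the list (camera with the preset correlation, Benjamini-Hochberg) was 1.08e-04, without T2 replicate 1. This argues against a single library only as the source of the list call at that correlation. Without T3 replicate 2, every nitrite oxidoreductase gene called singly for T3 vs T2 kept its direction and lost the threshold. Reads shared between similar copies could spread a change in 1 copy over others, but the log2 ratio of the other alpha copies to NITMOv2_RS20860 differed between T2 and the other days by 0.30 (SE 0.24), which leaves this undecided. A change in the culture between the days stays open, since there was 1 reactor and nothing here tests it.

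The ribosomal protein list, which passed between T1 and T3 only with the preset correlation (camera, Benjamini-Hochberg adjusted p 0.221 with an estimated one), holds short genes, with a median length of 396 bp. Of 10000 lists of other genes with matched lengths, 11.6% had a median log2 fold change at least as high as the list's 0.24, where the matched median was 0.13. With the trend over gene length removed, the list median was 0.16 and the adjusted p 0.287 (camera with the preset correlation, Benjamini-Hochberg). Gene length as the source is therefore undecided. In libraries thinned to the same total the list median was 0.25 and the adjusted p (camera, Benjamini-Hochberg) 0.00593 with the preset correlation (0.221 with an estimated one in the full libraries), which argues against depth as the source of the preset-correlation call.

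The pairwise T2 vs T3 columns of the authors' deposited table hold what adding the day coefficients of the model gives, where the comparison needs their difference. A DESeq2 refit with added coefficients gave the deposited p within 0.01 for 99.98% of genes, and the subtracted contrast for 1.90%. Fold changes and standard errors each matched the added refit for 4266 of 4267 genes. The subtracted contrast matched them for 21 and 0, which argues against a subtracted contrast. The median SE of the pairwise columns in the authors' deposited table was 1.52, against 0.93 in the time-course columns.

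The libraries of the days compared were also split into other groups of 3 to see what groupings that mix the days would give. Every other split of a pair of days puts libraries of both days in each group. It keeps part of the day difference and adds the rest to the spread within groups, which can lower its calls. The other splits therefore do not show what libraries without a day difference would give. Between pairs of days there are 10 splits, too few for a share under 0.05. The real split gave 9, 10 and 15 changed genes in T2 vs T1, T3 vs T2 and T3 vs T1, and the highest other split 1, 2 and 4, so that 1 split, the real one, was as large in each. For genes changed at least 2-fold the real values were 3, 5 and 12 and the highest others 1, 2 and 4, again with 1 split as large in each. For gene lists the real values were 2, 1 and 1 and the highest others 2, 2 and 1, with 2, 3 and 3 splits as large. For equivalent genes between T1 and T3 the real value was 865 and the highest other 956, with all 10 splits as large. Over the 3 days the real split gave 30 genes and the highest other of 100 splits 18. Only 1 split, the real one, was as large, which argues against an accidental grouping of the libraries. The libraries of a day are technical replicates, so this says only that they resembled each other more than those of other days.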
